A study of Mus musculus with 16 samples.

How the data were processed

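RNA-seq libraries from splenic CD19-positive B cells of C57BL/6 mice, cultured with LPS for 72 hours, were compared between 4 groups. The libraries were made with a stranded mRNA kit from RNA purified on micro columns, per the labels' protocols. The authors deposited raw read counts per gene, 1 column per library, with no normalization, as whole numbers whose sums differ between libraries. The genome build was mm9, per the submitters' processing notes. The aligner, the counting tool and its strand setting, and the gene models are not given in the sources used here. The deposited table also lists a length in bases for each gene, which was not used. Genes that overlap or have near-identical copies are therefore uncertain, since reads from them could be split, shared or dropped.

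The table held 21761 numeric gene IDs, of which 21615 were matched to symbols through a RefSeq table of assembly GRCm38.p6. That table was used for names, for which genes neighbour each other, and for X or Y linkage; no coordinate is given because the builds differ. The 146 unmatched IDs held 0.11% of counts and were kept. The table had no entry for immunoglobulin gene segments or mitochondrial genes, which were not analysed here. Group and replicate of each library came from its title. No pair of libraries of the same group agreed within sampling noise, so each counted as 1 replicate. That check cannot tell whether libraries shared mice or cultures. Chi-square per degree of freedom, about 1 for sampling noise, was 5.45 for PU1 knockouts 1 and 2. It was 6.66 for PU1 wild types 1 and 2 and 7.41 for OBF1 knockouts 1 and 3. All other pairs within a group lay at 14.8 to 133.

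Differential expression was tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts. Genes were filtered with filterByExpr, libraries scaled by the trimmed mean of M-values (TMM), and each comparison fitted with the quasi-likelihood test. Each knockout was fitted with its own controls alone. The difference of the knockout effects was fitted over all 16 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. CPM values are counts per 1e6 of the TMM-scaled totals, scaled over the libraries in the comparison, and values after ± are SDs over replicates. Exceptions are Xist, the sums of Y-linked genes and the Ddx3y values among the flagged results, which are per 1e6 of the unscaled library total. The log2 CPM behind the list tests and the principal components used a prior count of 2. The log2 changes came from the edgeR fit with its default prior count. With 1 to 3 counts in a group, the ratio is given with a 95% counting interval, and with 0 counts as a lower bound against 3 counts over the group. Such intervals and bounds cover counting error only.

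There were 30 gene lists with 497 members, of which 491 were matched. They were tested with camera of limma 3.58.1 on log2 CPM at a preset correlation of 0.01, and again with an estimated correlation, each adjusted over the lists of a comparison. No list with a preset call in a comparison of knockout and wild type, in the difference of effects or between wild types had an adjusted p under 0.05 with an estimated correlation. Lists with under 3 tested members gave values only. The lists, the comparisons, the tests and the rule for named genes were fixed before the data were examined. That rule took Spi1, Spib, Pou2af1, Pou2f1 and Pou2f2. It took the 8 largest rises and 8 largest falls among called genes with at least 10 CPM in the higher group and no overlap between groups, leaving out clone-named genes and antigen-receptor segments. It also took up to 4 members of each list with the smallest adjusted p. For the difference of effects it took the 5 largest of each sign, and between wild types the 3 largest.

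On simulated counts with known changes, the fit for the libraries labelled PU1 knockout (12091 genes) recovered 51.7% of 60 genes changed 1.5-fold, 89% of 73 changed 2-fold and 95.5% of 67 changed 4-fold, with 10 false calls. The OBF1 fit (12048 genes) recovered 61.7%, 86.3% and 86.6%, with 13 false calls. The difference of effects (12636 genes) recovered 19.4% of 62, 77.5% of 71 and 83.6% of 67, with 6 false calls. Simulated genes varied independently, without structure among the libraries, and fewer of them changed than were called in the data. The false calls therefore do not measure those in the real libraries.

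Alternatives were size factors as DESeq2 makes them, no filter on low counts, DESeq2 1.42.0, limma-voom, a 2-fold threshold, all groups fitted together, the replicate number as a block, all 8 wild types as the OBF1 control, fry in place of camera, and each library left out in turn. Chosen after seeing the data were X- and Y-linked genes left out, female wild types only, PU1 lists without wild-type replicate 4, and the first surrogate variable of sva 3.50.0 as a covariate.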

Results

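Gene expression was measured by RNA-seq in mouse splenic B cells after 72 hours of culture with 50 µg/ml lipopolysaccharide (LPS), a bacterial wall component that drives B cells to divide and to start secreting antibody. The cells carried the CD19 surface marker of B cells and had been bound to magnetic beads through it. The 16 libraries fell into 4 groups. They were 5 labelled PU1 knockout, their 5 wild-type controls, 3 labelled OBF1 knockout, and 3 further wild types taken as the controls of the OBF1 knockout because their titles share its pattern. PU.1, encoded by Spi1, is an ETS-family transcription factor of B and myeloid cells, and OBF1, encoded by Pou2af1, is a B-cell coactivator that binds the Oct factors on DNA. The series title concerns OBF1, the Oct factors and the germinal centre program, so the first question for each knockout was which genes of the B-cell programs moved. Total counts per library averaged 32.4 ± 5.5 M (SD, n = 5) in the PU1 knockouts, 38.9 ± 4.9 M (n = 5) in their controls, 31.1 ± 4.1 M (n = 3) in the OBF1 knockouts and 37.8 ± 3.7 M (n = 3) in theirs. The labels do not say that replicates came from separate mice, so the p-values measure the spread between these libraries, which may be technical. All levels are in CPM (counts scaled to the library total, as the processing text sets out), all changes are knockout over wild type, and adjusted p-values are from edgeR unless another test is named.

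The gene named by each knockout was examined first. Pou2af1 (gene ID 18985) was nearly lost in the OBF1 knockout, at 14.0 ± 0.98 CPM (SD, n = 3) against 617 ± 26.8 CPM in its controls, 44.1-fold lower (log2 change -5.46, SE 0.09, adjusted p = 1.25e-09). Spi1 (gene ID 20375) went against its label: it stood at 72.4 ± 3.62 CPM in the 5 libraries labelled PU1 knockout and at 31.8 ± 2.48 CPM in their controls, 2.27-fold higher (log2 change 1.19, SE 0.075, adjusted p = 2.26e-06). A count per gene does not show which exons the reads came from, so it does not tell whether part of Spi1 was missing. The direction of every change below is that of the libraries labelled PU1 knockout. The tested gene next to Spi1 is Mybpc3 (gene ID 17868), which encodes a myosin-binding protein of heart muscle, and it rose from 1.54 ± 0.07 to 569 ± 25.1 CPM in the same libraries, with adjusted p = 5.16e-15. Pou2af1 itself was 1.55-fold higher in the libraries labelled PU1 knockout (adjusted p = 0.00524). Spi1 was 1.23-fold higher in the OBF1 knockout (adjusted p = 0.0322), a call that ended without knockout replicates 2 or 3 or wild-type replicate 3. Spib, a close relative of Spi1, did not pass the test in either experiment, at 887 ± 96.7 against 844 ± 31.7 CPM for PU1 and 505 ± 29.3 against 541 ± 27 CPM for OBF1. Neither Oct factor gene, Pou2f1 or Pou2f2, passed it, with log2 changes of 0.66 and 0.58 for PU1 and of -0.04 and 0.08 for OBF1.

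**Figure D1:**
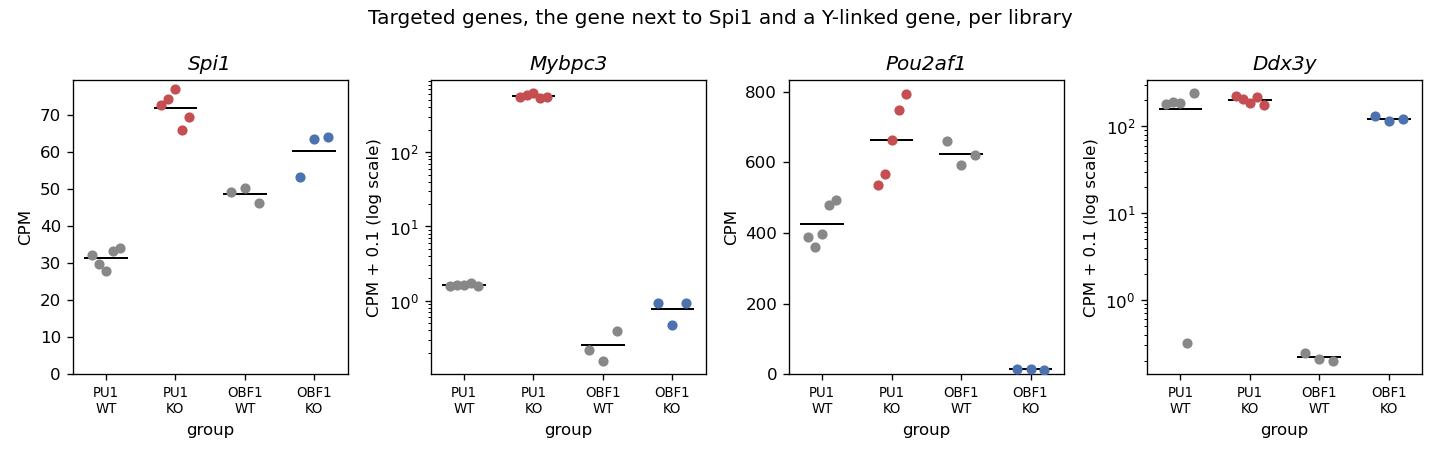
Expression of Spi1, Mybpc3, Pou2af1 and Ddx3y in the 16 libraries, 1 point per library with a line at the group mean; Spi1 and Pou2af1 are in CPM from 0, and Mybpc3 and Ddx3y in CPM plus 0.1 on a log scale. Scaled over all libraries, Spi1 averaged 71.9 CPM in the labelled PU1 knockouts and 31.5 CPM in their controls, Mybpc3 averaged 566 and 1.52 CPM, Pou2af1 averaged 14.3 CPM in the OBF1 knockouts and 625 CPM in their controls, and Ddx3y was below 1 CPM in the OBF1 wild types and in 1 PU1 wild type.

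The libraries labelled PU1 knockout showed a rise of plasma cell and secretory genes and a fall of interferon-response genes. Of 12091 genes tested, 853 were higher and 646 lower, and 366 and 97 of these changed at least 2-fold. Among genes of at least 10 CPM in the higher group whose groups did not overlap, clone-named genes left out, the largest rises after Mybpc3 were in Wnt10a, a secreted signalling protein, 12.2-fold to 13.1 ± 3.89 CPM, Srgap3 at 8.35-fold, Ackr3, a scavenging chemokine receptor, at 7.56-fold, Cpeb3 at 6.7-fold, Cacna1h, a calcium channel subunit, at 5.79-fold, Atp1b1 at 5.73-fold and Nrp1 at 5.4-fold. Their adjusted p-values ran from 4.97e-07 for Ackr3 to 0.00591 for Cacna1h. The largest falls within these limits were in Plbd1, from 79.7 ± 7.49 to 15.7 ± 1.98 CPM (5.06-fold, adjusted p = 8.21e-08), Ryr1, a calcium release channel, at 3.69-fold, Nxpe2 at 3.26-fold, Kmo, an enzyme of tryptophan breakdown, at 3.04-fold, and Cd300lf at 3.03-fold. Gsn, an actin-severing protein, fell 2.81-fold, Slamf1, a lymphocyte surface receptor, 2.74-fold and Oas3, an interferon-induced antiviral enzyme, 2.64-fold. The count of lower genes was 428 without PU1 knockout replicate 4 and 385 without wild-type replicate 3. Wild-type replicate 4 was the only one of the 10 libraries with female expression, at 557 CPM of Xist.

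Genes of plasma cells, the antibody-secreting cells that LPS-driven B cells give rise to, were mostly higher in the libraries labelled PU1 knockout. Of 19 tested, 14 rose and 1 fell, and 16 and 1 when adjusted over the list alone. Txndc5, a disulphide isomerase, rose 2.72-fold to 376 ± 80.6 CPM, Creld2 2.28-fold, Fkbp11 3.82-fold, and Xbp1, a transcription factor that secretory cells depend on, 2.73-fold from 183 ± 46 to 501 ± 138 CPM. Prdm1, the plasma cell regulator Blimp-1, rose from 22.9 to 72.4 CPM (adjusted p = 0.00281) and Jchain, which joins secreted antibody units, from 39.4 to 118 CPM (adjusted p = 0.023); both were chosen after their values were seen. The list stood apart from other genes with adjusted p = 1.4e-10 by camera, and adjusted p = 0.2 with an estimated correlation. Among 26 genes of the unfolded protein response and secretion, 17 rose and none fell, 20 adjusted over the list alone (camera adjusted p = 1.3e-10, and adjusted p = 0.2 with an estimated correlation). Examples were Pdia4 at 1.94-fold, Dnajc3 at 1.57-fold and Hsp90b1, an endoplasmic reticulum chaperone, at 1.88-fold. In the same comparison Malat1, a nuclear RNA chosen after its values were seen, was at 10300, 10350 and 15010 CPM in knockout replicates 3, 4 and 5 and at 5909 and 4833 CPM in replicates 1 and 2, and those 3 libraries also stood apart from the other 2 in the principal components.

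Interferon-response genes were lower. Of 20, 13 fell and none rose, and adjusted over the list alone 16 fell and 1 rose. Rsad2 fell 2.37-fold from 78.5 ± 7.61 to 33.2 ± 5.49 CPM, Usp18 2.01-fold, Ifit1 1.73-fold and Mx1 1.6-fold, with adjusted p-values of 3.3e-05 to 0.000128 (list adjusted p = 1.3e-10 by camera, and adjusted p = 0.13 with an estimated correlation). Of 15 genes of the integrated stress response, which senses lack of amino acids among other stresses, 6 fell, among them Sesn2, Ddit3 and Mthfd2, and 1, Slc7a11, rose; adjusted over the list alone 8 fell and 1 rose. Slc7a11 was chosen after its values were seen, and the rise was lost without wild-type replicate 2 or 3. The list had adjusted p = 0.001 by camera and adjusted p = 0.2 with an estimated correlation. Genes of B cell survival and apoptosis gave 4 falls and no rise among 15, and 7 falls adjusted over the list alone (camera adjusted p = 0.016, and adjusted p = 0.2 with an estimated correlation). With DESeq2, or with the 4 groups fitted together, 7 fell. Pmaip1 and Bbc3, which encode the death-promoting proteins NOXA and PUMA, fell 1.84-fold and 1.51-fold.

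Germinal centre genes moved both ways in the libraries labelled PU1 knockout, with 3 higher and 5 lower of 22, 4 and 6 adjusted over the list alone, and the list did not stand apart (camera adjusted p = 0.18, and adjusted p = 0.22 with an estimated correlation). Lmo2 fell 1.92-fold, Basp1 2.18-fold and Mef2b 1.45-fold, while Myb rose 1.36-fold. Aicda, the enzyme that mutates antibody genes, rose 1.67-fold (adjusted p = 0.0301), a call that ended in 5 of the 10 fits that left out 1 library (knockout replicate 5 and wild-type replicates 1, 2, 3 and 4) and with the first surrogate variable as a covariate, where the log2 change stayed at 0.74. Without wild-type replicate 2, 3 or 4 a single member of the list was higher. Of 14 genes of antigen presentation on MHC class II, 2 fell, the costimulators Cd86 at 1.69-fold and Cd80 at 1.39-fold, and 3 adjusted over the list alone (camera adjusted p = 0.0021, and adjusted p = 0.22 with an estimated correlation); the Cd80 call ended in 4 of the 10 fits, without knockout replicates 1 or 5 or wild-type replicates 1 or 3. Among 16 marginal zone genes 6 rose and 2 fell, the same counts adjusted over the list alone, with Myof at 3.52-fold, Asb2 at 3.86-fold and Tbc1d9 at 2.09-fold (camera adjusted p = 0.015, and adjusted p = 0.2 with an estimated correlation). Cytokines gave 6 rises and 1 fall among 15, 6 and 2 adjusted over the list alone, led by Il10 at 2.58-fold and Csf2 at 6.31-fold, with Ebi3 1.76-fold lower (camera adjusted p = 0.019, and adjusted p = 0.2 with an estimated correlation). Of 25 cell cycle genes, 2 rose, Mki67 and Ccne1, and none fell, the same adjusted over the list alone (camera adjusted p = 0.62, and adjusted p = 0.89 with an estimated correlation). Neither rise was called without knockout replicate 4 or wild-type replicate 4, and 1 was without wild-type replicate 1 or 3. Genes of ribosome production, cholesterol synthesis and oxidative phosphorylation gave 0 calls by edgeR among 20, 18 and 22 tested.

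Some markers of other cell types rose in the libraries labelled PU1 knockout. Of 15 T cell genes listed, only 6 could be tested, as could 1 of 10 NK cell genes and 0 of 12 neutrophil genes. Of the 6 T cell genes, 5 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.00014, and adjusted p = 0.13 with an estimated correlation). Zap70 rose from 0.352 to 4.22 CPM, Cd247 from 0.215 to 0.779 CPM, Tcf7 from 0.458 to 1.95 CPM and Lck from 33.8 to 56.6 CPM. Prf1, of cytotoxic cells, rose from 0.816 to 5.17 CPM. Of 10 macrophage and monocyte genes 2 rose and none fell, 3 adjusted over the list alone (camera adjusted p = 0.015, and adjusted p = 0.37 with an estimated correlation). They were Lyz2, from 1.54 to 4.73 CPM, and Adgre1, from 7.82 to 10.7 CPM, a call that ended without knockout replicate 1, 2 or 3 or wild-type replicate 1, 2, 3 or 4. Kdr, an endothelial receptor, fell 9.41-fold from 3.06 to 0.31 CPM (adjusted p = 0.000139), and it was the 1 call among 3 stromal and endothelial genes, 1 adjusted over the list alone (camera adjusted p = 0.18, and adjusted p = 0.27 with an estimated correlation). Flt3, a growth factor receptor on progenitors and dendritic cells, fell 2.06-fold from 222 ± 8.68 to 107 ± 8.64 CPM.

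**Figure D2:**
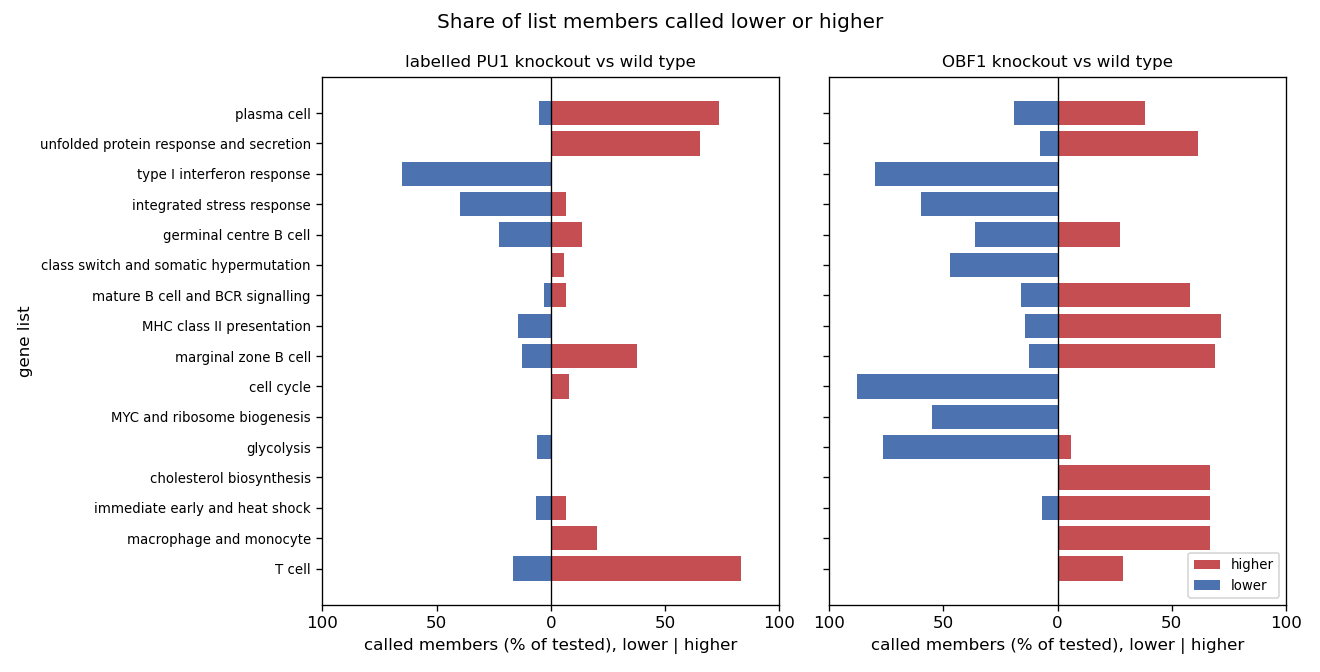
Share of the tested members of 16 gene lists that passed the test, in percent, to the right for higher and to the left for lower in the knockout libraries; the left panel shows the libraries labelled PU1 knockout and the right panel the OBF1 knockout. Of cell cycle genes, 22 of 25 were lower in the OBF1 knockout, and of plasma cell genes, 14 of 19 were higher in the libraries labelled PU1 knockout.

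In the OBF1 knockout, genes of cell division, glycolysis and the interferon response were lower, and genes of the B-cell receptor, marginal zone B cells, MHC class II, cholesterol synthesis and the immediate early response were higher. Of 12048 genes tested, 2156 were higher and 2193 lower, and 633 and 390 changed at least 2-fold. The sexes were not balanced: the 3 knockout libraries held both Xist (145, 173 and 157 CPM) and Y-linked transcripts, and the 3 wild types held Xist (313, 190 and 240 CPM) with at most 0.3 CPM summed over 4 Y-linked genes. Within the limits set for named genes (at least 10 CPM in the higher group, no overlap between groups, clone-named genes left out), those genes gave the largest rises, with Ddx3y at 120 ± 8.75 CPM against 0.117, Kdm5d at 42.8 against 0.0363 and Uty at 37.8 against 0.0379. Eif2s3y rose to 81.4 CPM over 3 counts in the wild types, a ratio of 2689 with a counting interval of 1050 to 14800. Within the same limits, Jhy rose to 26.7 ± 1.19 CPM over 3 wild-type counts (counting interval of the ratio 341 to 4850), and Fnip2 rose 79.7-fold to 18.7 CPM. The largest falls within them were in Zfp811, from 18.8 ± 2.11 to 0.398 ± 0.191 CPM (46-fold), Pou2af1, Eps8l1 at 25.6-fold, Hnf1b at 16.7-fold, Slc16a3, a lactate exporter, at 16.2-fold, Gfi1b, a transcriptional repressor of blood cells, at 15.9-fold, Elovl7 at 10.3-fold and Fam81a at 9.63-fold. Without wild-type replicate 3 the count of lower genes was 1405. With all 8 wild types as control the calls of Slc16a3 and the 4 Y-linked genes ended, the latter with log2 changes of 0.20 for Eif2s3y, 0.31 for Ddx3y, -0.20 for Kdm5d and -0.34 for Uty. That control, here and below, pools the OBF1 and PU1 wild types, which differed from each other in 5370 genes.

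Of 25 cell cycle genes, 22 were lower in the OBF1 knockout and none higher, the same adjusted over the list alone (camera adjusted p = 8.1e-09, and adjusted p = 0.18 with an estimated correlation). Bub1, a mitotic checkpoint kinase, fell 2.24-fold from 88 ± 9.5 to 39.3 ± 1.51 CPM, Aurka 2.19-fold, Birc5 1.97-fold and Mcm5, a part of the replicative helicase, 1.74-fold. Glycolysis genes gave 13 falls and 1 rise among 17, the same adjusted over the list alone (camera adjusted p = 0.00014, and adjusted p = 0.18 with an estimated correlation), with Tpi1 2.52-fold, Pgk1 2.37-fold and Aldoa 1.92-fold lower. The 1 rise was lost in each fit that left out 1 library. With all 8 wild types as control 5 of the 17 were lower, and the calls of Tpi1, Pgk1 and Aldoa ended. Among 20 genes of the MYC and ribosome production program 11 fell, the same adjusted over the list alone, led by Ncl at 1.9-fold and Npm1 at 1.51-fold (camera adjusted p = 0.0012, and adjusted p = 0.18 with an estimated correlation). The Ncl call ended with all 8 wild types as control and with the 4 groups fitted together. The count of the list was 6 without knockout replicate 3, 7 without wild-type replicate 3 and 4 with the 4 groups fitted together. Of 20 interferon-response genes 16 fell, 18 adjusted over the list alone, with Gbp2 1.77-fold, Irf7 1.57-fold and Oasl1 1.54-fold lower (camera adjusted p = 4.4e-06, and adjusted p = 0.18 with an estimated correlation).

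Germinal centre genes moved both ways in the OBF1 knockout, with 6 higher and 8 lower of 22, 6 and 9 adjusted over the list alone, and the list did not stand apart (camera adjusted p = 0.81, and adjusted p = 0.8 with an estimated correlation). Bcl6, a transcriptional repressor that germinal centre B cells depend on, rose 1.99-fold from 24.6 ± 2.64 to 49.1 ± 2.49 CPM, and Cxcr4 rose 2.06-fold. Lmo2 fell 1.95-fold and Cxcr5, the receptor that leads B cells into follicles, 1.85-fold. The count of lower members was 5 without knockout replicate 1 and 4 with all 8 wild types as control, where the Lmo2 call ended. Of 17 genes of class switching and somatic hypermutation 8 fell, and 10 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.0024, and adjusted p = 0.24 with an estimated correlation). Aicda fell 1.76-fold from 338 ± 20.5 to 192 ± 18.6 CPM (adjusted p = 0.000116), and its log2 change with all 8 wild types as control was -0.01. Plasma cell genes gave 8 rises and 4 falls among 21, 10 and 4 adjusted over the list alone, and the list did not stand apart (camera adjusted p = 0.16, and adjusted p = 0.36 with an estimated correlation); its median log2 change was 0.30 and its mean -0.34. Pou2af1, the targeted gene, is a member, and without it 8 rose and 3 fell of 20, with a median of 0.31 and a mean of -0.09. Sdc1, the plasma cell surface marker CD138, rose 4.07-fold from 13.7 ± 0.44 to 55.8 ± 1.58 CPM. Fitting the 4 groups together left 5 rises, and all 8 wild types as control left 2 falls. Genes of the unfolded protein response gave 16 rises and 2 falls among 26, the same adjusted over the list alone, with Dnajb9 at 2.24-fold and Hspa5 at 1.88-fold (camera adjusted p = 0.0003, and adjusted p = 0.3 with an estimated correlation). A single fall was left without knockout replicate 1, 2 or 3 or wild-type replicate 3, and with all 8 wild types as control.

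Genes of the mature B cell and its receptor rose in the OBF1 knockout, 18 of 31 against 5 that fell, and 18 and 6 adjusted over the list alone (camera adjusted p = 0.023, and adjusted p = 0.18 with an estimated correlation). Blk, a receptor-linked kinase, rose 2.13-fold and Fcrla 2.15-fold, whereas Fcer2a, the low-affinity IgE receptor CD23, fell 5.26-fold from 190 ± 14.9 to 36.1 ± 2.09 CPM and Vpreb3 4.17-fold. With all 8 wild types as control 3 were lower, and the Vpreb3 call ended; 3 were also lower without knockout replicate 3. Of 14 MHC class II genes 10 rose, and Cd86 and Cd80 fell, the same counts adjusted over the list alone (camera adjusted p = 0.0037, and adjusted p = 0.19 with an estimated correlation). Cd80 was named after its values were seen, and 1 fall was left without knockout replicate 1, 2 or 3 or wild-type replicate 1, with all 8 wild types as control and with the 4 groups fitted together. H2-Ob rose 1.59-fold and Cd74 1.26-fold. Marginal zone genes gave 11 rises and 2 falls among 16, 11 and 3 adjusted over the list alone, with S1pr1, a receptor that guides exit from tissues, 5-fold higher at 327 ± 12.3 CPM, Myof 4.7-fold and Cd9 3.15-fold higher (camera adjusted p = 0.0024, and adjusted p = 0.18 with an estimated correlation). With all 8 wild types as control 7 rose and 1 fell.

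Cholesterol synthesis genes gave 12 rises and no fall among 18, and 13 rises adjusted over the list alone (camera adjusted p = 0.00014, and adjusted p = 0.18 with an estimated correlation). Insig1 rose 2.56-fold and Msmo1 1.73-fold, and Ldlr rose 2.05-fold and Sqle 1.54-fold, calls that ended with all 8 wild types as control, where 5 members rose. Of 15 immediate early and heat shock genes 10 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.00032, and adjusted p = 0.18 with an estimated correlation). Fos rose from 1.48 ± 0.479 to 94.9 ± 28 CPM, Fosb from 0.228 to 10.5 CPM, Egr1 15.1-fold and Egr2 11.6-fold, and the calls of Fos and Fosb ended with all 8 wild types as control. The fall was in Atf3, chosen after its values were seen, from 75.3 to 48 CPM, and 2 fell without wild-type replicate 1. Integrated stress response genes gave 9 falls among 15, 11 falls and 1 rise adjusted over the list alone, with Mthfd2 and Asns 1.59-fold and 1.56-fold lower (camera adjusted p = 0.0012, and adjusted p = 0.18 with an estimated correlation). With all 8 wild types as control 5 fell and the Asns call ended. Cytokines moved both ways, with 6 rises and 7 falls among 16, the same adjusted over the list alone, and the list did not stand apart (camera adjusted p = 0.97, and adjusted p = 0.97 with an estimated correlation). Il10 rose 5.67-fold from 17.3 ± 1.53 to 98.3 ± 5.25 CPM and Ccl3 2.37-fold, while Cxcl10 fell 2.29-fold, a call that ended with all 8 wild types as control, where 4 fell. Tnf rose 2-fold, with a log2 change of -0.29 against all 8 wild types. Genes of B cell survival and apoptosis gave 9 falls and 1 rise among 15, 11 and 1 adjusted over the list alone (camera adjusted p = 0.0012, and adjusted p = 0.18 with an estimated correlation). Those of oxidative phosphorylation gave 9 falls among 22, 10 adjusted over the list alone (camera adjusted p = 0.0069, and adjusted p = 0.46 with an estimated correlation), and 4 without knockout replicate 2 or with all 8 wild types as control and 5 without wild-type replicate 3.

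Macrophage markers gave 6 rises among 9, the same adjusted over the list alone (camera adjusted p = 0.00033, and adjusted p = 0.18 with an estimated correlation). Adgre1, which encodes F4/80, rose 8.43-fold from 8.92 ± 0.525 to 75.2 ± 4.72 CPM, Marco from 1.06 to 5.57 CPM and Lyz2 from 0.525 to 3.11 CPM. Of 6 dendritic cell genes, which belong to other antigen-presenting cells, 4 rose and 1 fell, 4 and 2 adjusted over the list alone, and the list did not stand apart (camera adjusted p = 0.084, and adjusted p = 0.23 with an estimated correlation). Siglech rose from 0 counts to 1.89 CPM (at least 71-fold), Itgax from 0.341 to 1.24 CPM, Cst3 from 52.9 to 82.5 CPM and Flt3 from 201 to 270 CPM. The Itgax call ended without wild-type replicate 3 and with all 8 wild types as control. The fall was lost without knockout replicate 2 or 3 or wild-type replicate 1, and 2 fell with all 8 wild types as control or the 4 groups fitted together.

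Whether the knockouts changed a gene differently was tested as the OBF1 effect minus the effect in the libraries labelled PU1 knockout. Of 12636 genes, 1390 had a more positive and 1225 a more negative change in the OBF1 knockout. Within the limits set for named genes, the 4 Y-linked genes and Fnip2 (log2 difference 5.89) led the first, and the calls of the 4 ended with limma-voom. Mybpc3 (-6.44), Pou2af1 (-6.09), Wnt10a (-5.55), Hnf1b (-5.01) and Eps8l1 (-4.86) led the second. Of 25 cell cycle genes, 14 had a more negative change in the OBF1 knockout and none a more positive one, and 20 adjusted over the list alone (camera adjusted p = 3.5e-07, and adjusted p = 0.29 with an estimated correlation). Glycolysis genes gave 10 of 17 in the same direction and 2 in the other, 11 and 2 adjusted over the list alone (camera adjusted p = 7.8e-05, and adjusted p = 0.22 with an estimated correlation). Of the 2, 1 was lost without OBF1 knockout replicate 1 or 2, OBF1 wild-type replicate 1 or 3, or PU1 wild-type replicate 4. MHC class II genes were more positive for 7 of 14, and 12 adjusted over the list alone (camera adjusted p = 0.00012), cholesterol synthesis genes for 8 of 18, and 11 (camera adjusted p = 0.00012), and immediate early genes for 9 of 15, and 9 (camera adjusted p = 0.0019). Each of these 3 lists had adjusted p = 0.22 with an estimated correlation. Plasma cell genes had 9 of 21 more negative and 1 more positive, 12 and 1 adjusted over the list alone (camera adjusted p = 0.00016, and adjusted p = 0.37 with an estimated correlation). Of the 9, 1 was Pou2af1, the targeted gene.

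Genes that rose in the libraries labelled PU1 knockout also rose in the OBF1 knockout more often than independent lists would give. Among 11759 genes tested in both, 326 were higher in both against 141 for independent lists (odds ratio 3.62, adjusted p = 1e-56, two-sided Fisher's exact test), and 199 were lower in both against 116.6 (odds ratio 2.14, adjusted p = 9.8e-16). Opposed calls were near independence, 141 against 147.8 and 126 against 111.2 (adjusted p = 0.54 and 0.14). At 2-fold in both, opposed calls also exceeded it, 46 against 9.8 and 15 against 3.9, beside 91 against 14.6 higher in both and 16 against 2.6 lower in both. The comparisons used separate control libraries. Fisher's test treats genes as independent, which they are not, so its p-values do not measure the spread between libraries. Across genes, which are not independent replicates, the log2 changes had Pearson's r = 0.157 and Spearman's rho = 0.221. The count lower in both was 125 without PU1 knockout replicate 4 and 121 without PU1 wild-type replicate 3.

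The wild-type sets differed from each other in more genes than either differed from its knockout. Of 12190 genes, 2794 were higher and 2576 lower in the OBF1 wild types than in the PU1 wild types. Trim12a was at 41.4 ± 5.43 CPM (SD, n = 3) against a single count in 5 libraries, a ratio with a counting interval of 1470 to 324000. Dkk3 was at 54.1 against 0.2 CPM, Trim30d at 95 against 3.07 CPM and Gdpd3 at 0.433 against 30.7 CPM, and Uty and Ddx3y were lower with the sexes of the libraries, calls that ended with limma-voom. Plasma cell genes were higher for 19 of 21 and lower for 1, the same adjusted over the list alone (camera adjusted p = 2.9e-10, and adjusted p = 0.26 with an estimated correlation), and interferon-response genes were lower for 17 of 20, also the same adjusted over the list alone (camera adjusted p = 1.1e-08, and adjusted p = 0.26 with an estimated correlation). Unfolded protein response genes were higher for 21 of 26 (camera adjusted p = 1.3e-08). Oxidative phosphorylation genes were higher for 14 of 22, and glycolysis genes for 10 of 17 with 2 lower (camera adjusted p = 0.00084 and 0.02). Of 18 cholesterol synthesis genes 9 were lower and 1 higher (camera adjusted p = 0.015). With an estimated correlation these lists had adjusted p = 0.26 to 0.57. The last 3 lists moved the opposite way in the OBF1 knockout. With only the female wild types, 3 against 1, 915 genes were higher and 848 lower; the lone library is assumed to vary like the others.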

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

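The check for a library far from the others of its group was planned for named genes in the groups of 5; the tests of the sexes were chosen after Xist and Y-linked counts had been seen. Of 54 groups of values checked, 7 had such a library, where chance gives about 1 in 20.

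Spib stood at 717 CPM in PU1 knockout replicate 3, with the others at 899 to 945. Wnt10a stood at 19.8 CPM in PU1 knockout replicate 5, with the others at 10.3 to 12.8, and at 2.14 CPM in PU1 wild-type replicate 5, with the others at 0.664 to 0.893. Ryr1 stood at 4.14 CPM in PU1 knockout replicate 2, with the others at 2.57 to 2.89, and at 13.2 CPM in PU1 wild-type replicate 4, with the others at 10 to 10.8.

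PU1 wild-type replicate 4 had 557 CPM of Xist, where the other 4 wild types had 0 to 0.18, and 0.22 CPM of Ddx3y, where they had 184 to 244; the other 9 libraries of that experiment were of male type. In the OBF1 experiment every knockout library held Xist at 145 CPM or more together with Y-linked transcripts. Their Xist was 58.5 to 70% of the mean of the OBF1 wild types and their Y-linked sum 48.5 to 54.8% of the mean of the male PU1 knockouts, so each library may hold cells or RNA of both sexes. Dosage of sex-linked genes does not account for the calls as a whole, since 3.29% of called genes were X- or Y-linked and 35.1% of tested X-linked genes were called against 36.1% of autosomal ones. A sex difference in autosomal genes between these libraries stays open, because all 3 knockouts were mixed and all 3 controls female.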

How the results depend on the processing

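The alternatives with X- and Y-linked genes left out, with female wild types only and with a surrogate variable, and the list counts without PU1 wild-type replicate 4, were chosen after the data were seen. Over all alternatives, 4002 changes of named genes kept their side of the threshold, 62 passed it newly, 140 ended as calls and 5 reversed. For lists these were 137, 27, 48 and 0. A change of sign counted as reversed only where either fit called it, so uncalled changes of sign are among those kept. Under fry, the germinal centre and plasma cell lists of the OBF1 knockout changed direction in this way. Unlike camera, fry does not set a list against other genes. Among lists said above not to stand apart, fry gave adjusted p = 0.0014 for germinal centre genes in PU1 (lower). For OBF1 it gave 0.00016 for dendritic cell genes (higher), 0.0064 for cytokines (higher), 0.51 for germinal centre and 0.58 for plasma cell genes. Reversed with all 8 wild types as OBF1 control were Kdm5d (-0.203), Uty (-0.342), Tnf (-0.288), Lck (-0.083) and Kdr (-0.45). For the Y-linked genes, 4 of the added controls are male. For Lck and Kdr, the added PU1 wild types were at 33.8 and 3.06 CPM, above the OBF1 knockouts at 22.1 and 1.35 CPM. The OBF1 wild types were at 8.33 and 0.0515 CPM, each value scaled within its own comparison. The reversals of Lck and Kdr thus follow the level of the added controls, and for Tnf the cause was not tested. At 2-fold, fewer genes pass by construction: 366 higher and 97 lower for PU1, 633 and 390 for OBF1, 491 and 564 for the difference, 613 and 611 between wild types, and 91 and 16 shared. With female wild types only, 915 were higher and 848 lower, with fewer libraries.

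Same-numbered knockout and wild-type libraries did not deviate together (correlations -0.254 to 0.084 for PU1 and -0.245 to 0.036 for OBF1), so no pairing by number was seen. Such correlations cannot exclude a shared mouse or day, of which the labels say nothing. With the replicate number as a block 646 were higher and 420 lower for PU1, 1463 and 1310 for OBF1, and 1114 and 949 for the difference.

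Without 1 library, PU1 counts ran from 597 to 1058 higher and 385 to 764 lower, OBF1 from 1518 to 2434 and 1405 to 2333, the difference from 1133 to 1460 and 979 to 1390, wild types from 1906 to 2834 and 2076 to 2905, and shared calls from 231 to 356 higher and 121 to 235 lower. Moves over 1.5 times were in lower genes: PU1 without knockout 4 (428) or wild type 3 (385), OBF1 without wild type 3 (1405), shared without PU1 knockout 4 (125) or PU1 wild type 3 (121). Without PU1 wild type 4 there were 705 and 451, with the surrogate variable 865 and 677, and without X- and Y-linked genes 2152 and 2055 for OBF1. Leaving out immunoglobulin genes was not run, since the table lists none. At this depth, with genes simulated as independent, 1.5-fold changes were recovered for 51.7% of genes in the PU1 fit, 61.7% in the OBF1 fit and 19.4% for the difference.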

Other observations

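Chosen after the result was seen were the tests of the loci next to Spi1 and Pou2af1 and of flanking DNA; the tests of a paralog, of the tuft cell list, of epithelial genes and of other splits were set before their results were seen, while the tuft cell test without Vav1 and Ptpn6 was chosen after. The genes 1810046K07Rik, Pou2f3, Avil, Trpm5 and Sh2d7 were chosen after their values were seen.

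Several genes used by tuft cells, which are chemosensory epithelial cells, were higher in the OBF1 knockout libraries. Pou2f3, the Oct factor that tuft cells depend on, stood at 7.02 ± 0.456 CPM (SD, n = 3) against 0 counts in the wild types, at least 263-fold higher. 1810046K07Rik, by background knowledge the mouse gene of a coactivator of Pou2f3, stood at 40.3 ± 5.15 against 0.19 CPM. Avil rose from 9.02 to 128 CPM, Trpm5, a taste-type ion channel, from 2.01 to 20.7 CPM, and Sh2d7 from 0 counts to 0.978 CPM (at least 36.7-fold). Gfi1b went the other way, from 11.9 to 0.749 CPM, and Spib, also used by tuft cells, did not pass the test (log2 change -0.098, adjusted p = 0.314). Of 40 tuft cell genes that had not been picked for this pattern, 27 were tested, and 23 were higher and none lower. Vav1 and Ptpn6 among them had already been counted in the B-cell receptor list, and without these 2, 21 of 25 were higher and none lower. Examples were Hpgds from 7.34 to 33.5 CPM, Hck from 61.3 to 198 CPM, Gnat3 from 0.0769 to 6.91 CPM and Alox5 from 0 counts to 2.95 CPM (at least 111-fold). Of the 27, 13 were at 10 CPM or more in the wild-type B cells, so the list is not specific to tuft cells. Members with 0 counts in the wild types, such as Alox5, passed the filter through the knockouts alone and could only come out higher.

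The median log2 change of those 27 genes was 0.90, at percentile 100 of 10000 random lists matched on expression. The medians of the random lists ran from -0.17 to 0.17 between their 5th and 95th percentiles. Without Vav1 and Ptpn6 the median was 1.17, also at percentile 100. Members such as Alox5 and Ascl2, with 0 counts in the wild types, could only come out higher, so the percentile was partly fixed in advance. Random genes were matched on the mean level of both groups, which does not remove this. The percentile is thus not taken here to exclude a chance draw. The list was not tested with an estimated correlation, so chance agreement of genes that move together between libraries stays open. Tuft cells from an epithelium stay open, although the spleen cells had been selected on beads through CD19, a step meant to leave out cells without it, whose purity was not analysed here. The 8 epithelial genes summed to 12.9 CPM in the knockouts, above the 7.02 CPM of Pou2f3 set beforehand as the bound for that explanation, and their summed rise was 8.31 CPM, above the 3.51 CPM under which it was to be dropped, with Krt18 and Epcam giving most of it. Against it, Cdh1 and Krt19 had 0 counts in all 6 libraries and Krt20 and Vil1 had 0 in the knockouts, values that were weighed only after the bound had been met, when the verdict was changed to open. A hypothesis is that B cells without Pou2af1 may express part of a Pou2f3 program; it was not tested, and counts from single cells, not used here, would show whether Pou2f3 and B-cell genes occur in the same cells.

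1810046K07Rik is the tested gene next to Pou2af1, so altered transcription at the targeted locus may raise it. It ranked 16 among all rises and so missed the top 10 set as the bound. The verdict was changed to open after that was seen, because 12 of the 15 genes above it had 3 wild-type counts or fewer, where the fitted change depends on the prior count; among the others it ranked 4. The 20 nearest tested genes moved by 0.903 times the median absolute change of all genes, and 7 of them were called, against 36.1% of all tested genes. A median over neighbours cannot decide on DNA of another strain around the target, which may change only some of them, so that stays open. The other neighbour, Sik2, had a log2 change of -0.43 (adjusted p = 0.11).

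Mybpc3 lies next to Spi1 on the same strand and downstream, and its rise ranked 1 of all genes in the libraries labelled PU1 knockout. Reads of a paralog are argued against, since the highest, Mybpc2, was at 0.8% of the Mybpc3 level. The 20 nearest genes other than Mybpc3 moved by 0.63 times the median of all genes, and 1 of them was called, against 12.4% of all tested genes. Such a median cannot decide on flanking DNA of another strain either, so that stays open. A candidate explanation for both rises is transcription that starts at an altered Spi1 and runs on into Mybpc3, which would also leave Spi1 counts in cells without the protein. An exchange of the knockout and wild-type labels is argued against by Mybpc3 at 0.156 CPM in the OBF1 wild types, a check chosen after the result was seen, and exon-level counts, not used here, would bear on what was left of Spi1.

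Chance is argued against as the source of the 1499 calls in the PU1 experiment. Of 100 splits of its libraries drawn from the 126 possible, 2 called as many, the real one included. The other one called 1666 genes and set knockout replicates 1 and 2 with wild types 3, 4 and 5, which follows the first surrogate variable and points to a structure of the samples. The share of splits alone does not separate the knockout from such a structure. The 4349 calls for OBF1 stood against 0 in the highest of the other 9 splits, but 10 splits are too few for a share under 0.05 (the real split was the 1 with as many). Between wild types chance is argued against: 1 of 56 splits, the real one, gave 5370, and the highest other 0. For the difference of effects 4 of 100 draws, the real one included, reached 2615, with a highest other of 3509. All 4 were among the 11 draws that kept the OBF1 labels whole or swapped them whole, and draws that mixed them gave at most 1. The OBF1 libraries allow 10 splits, too few to weigh their labels, and with those labels kept some shuffled PU1 labels gave as many calls, so the share of draws is not taken here to exclude chance.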
